A study of Mus musculus with 12 samples.

How the data were processed

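Total RNA from the livers of 12 BALB/c mice, extracted with Trizol and labelled with biotin by a one-cycle protocol per the labels, was measured on 12 arrays of 45101 probe sets. The deposited values are linear signal intensity per probe set. From the values, the mean of each array without its lowest and highest 2 percent lies between 149.9 and 150, so each array had been scaled to a common trimmed mean before deposit. The signal algorithm and the scaling target are not given in the sources used here, and detection calls were not analysed here. The samples were grouped by their labels into 4 groups of 3 arrays, 1 mouse each. Replicate 1 of IFNko TGFB+ has no number in its label and was given the number left over. The array medians of log2(signal + 16) differed by 0.634, above the 0.5 set before the data were examined as the limit for quantile normalization, and that gap rests on the array IFNko TGFB1 KO 1 (6.272), as the other 11 lay between 5.638 and 5.874. Quantile normalization was therefore applied to the 12 arrays after adding a pseudocount of 16 and taking log2. Fold changes on this scale understate those of dim genes.

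Of the 45101 probe sets, 34958 carry a single gene symbol, 932 carry several and 9211 have none listed. Of the single symbols 34754 were updated through the gene identifier with a RefSeq table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. The 64 control probe sets were left out, as were probe sets whose mean lay under the 40th percentile (a log2 level of 5.25). Each gene was represented by the probe set with the highest mean among those with a single symbol, which left 12755 genes for testing. Probe sets with no or several symbols were tested apart.

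Groups were compared in R 4.3.3 with limma 3.58.1, using lmFit with a mean per group over all 12 arrays and eBayes (8 residual and 3.44 prior degrees of freedom). The 5 contrasts were TGFB KO against wild type, IFNko TGFB1 KO against IFNko TGFB+, the difference of these TGFB effects, IFNko TGFB1 KO against TGFB KO, and IFNko TGFB+ against wild type. P-values are two-sided, with Benjamini-Hochberg adjustment over the 12755 genes and a threshold of 0.05, and rest on 3 mice per group. Values after ± are standard errors of log2 fold changes unless given as SD. No pairing of the samples was used. Shifts of 32 gene lists (20 pathway and 12 cell type lists) were tested with camera at an inter-gene correlation of 0.01, adjusted over the 32 lists of a contrast, beside camera with an estimated correlation and fry. The lists hold 544 genes, of which 484 have a probe set with a single symbol and 443 were tested. Members were also adjusted over their list alone. Some lists share genes, so lists that pass together are not separate evidence. The IFN-gamma inducible list shares Cxcl9, Cxcl10 and Icam1 with the chemokine list, for example. It also shares Psmb8, Psmb9 and Tap1 with the MHC class I list and Ciita with the MHC class II list. The Th1 and cytotoxic effector list includes the targeted gene Ifng. Gene lists, tests, contrasts, alternatives and the rule for named genes were fixed before the data were examined.

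The genes named are Tgfb1 and Ifng, the 10 largest rises and the 10 largest falls of the first 2 contrasts and the 6 of each in the others, and up to 4 list members with the smallest p per list and contrast. The largest changes were taken among genes past the threshold, without overlap between the arrays compared (except for the difference of effects), and predicted or clone names were passed over. Fold changes of the first 2 contrasts, which share no arrays, were compared across genes by correlation and by overlap of calls. For contrasts that share arrays, 100 simulations without effects gave the values due to sharing. The sex of each mouse was read from Xist and Eif2s3y.

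The procedure was tested on simulated data made from the 12 arrays, with 100 genes changed 2-fold and 100 changed 4-fold among 12755. It recovered 53 and 93 percent of them for TGFB KO against wild type, 39 and 79 percent for IFNko TGFB1 KO against IFNko TGFB+, 9 and 63 percent for the difference of effects, 43 and 83 percent for IFNko TGFB1 KO against TGFB KO, and 36 and 67 percent for IFNko TGFB+ against wild type. None was called in the wrong direction, and 15, 6, 12, 7 and 5 unchanged genes were called in these contrasts. The simulated noise was independent between genes and had the same spread per gene in each contrast, with a single draw per contrast. Differences among the contrasts other than the difference of effects therefore reflect that draw, not the groups. The data hold more changed genes (3077 and 3292 called in the first 2 contrasts), so these percentages need not carry over to them.

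The results were recomputed, each where the alternative applies to it, with the deposited scaling, median centring, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets ending in _x_at or _s_at left out, every probe set, only the arrays compared, an intensity trend, arrayWeights, a replicate block, a 2-fold threshold, an ordinary t statistic, and each array left out in turn. Every probe set, the 2-fold threshold and the t statistic apply to counts of genes, the t statistic not to the difference of effects, and the fit of only the arrays compared not to results that use all 12. Leaving out a single array keeps 2 in its group. Added after seeing the data were all steps repeated without the array IFNko TGFB1 KO 1, sex as a covariate, and the ratio of the 3' to the 5' Gapdh control probe set as a covariate.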

Results

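Liver RNA of 12 BALB/c mice was profiled on 12 oligonucleotide arrays of 45101 probe sets each. The labels divide the arrays into 4 groups of 3, namely wild type, TGFB KO, IFNko TGFB+ and IFNko TGFB1 KO. In the series design these are mice lacking transforming growth factor beta 1 (Tgfb1), mice lacking both Tgfb1 and interferon gamma (Ifng), and littermates that keep Tgfb1, in a study of acute autoimmune hepatitis. TGF-beta1 is a cytokine that restrains lymphocyte activation, and IFN-gamma is the main cytokine of type 1 T helper (Th1) cells. The groups therefore ask what loss of Tgfb1 does to the liver and how much of it depends on Ifng. The labels do not say whether the IFNko TGFB+ mice carry 1 or 2 intact copies of Tgfb1. Every array had a trimmed mean signal between 149.9 and 150, and 11 of them had a median signal between 33.8 and 42.6. The array IFNko TGFB1 KO 1 stood apart, with a median of 61.3 and a rank correlation of 0.754 to 0.809 with the other arrays, against 0.816 to 0.912 among the other 11. Arrays of RNA from 1 female and 2 male mice, as read from Xist and Eif2s3y, made up each group.

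The targeted genes were read first. The Tgfb1 probe set used for the gene had a mean signal of 319 ± 184 (SD, n = 3) in wild type, 68.1 ± 21.2 in TGFB KO, 188 ± 29.5 in IFNko TGFB+ and 40.2 ± 13.9 in the arrays labelled IFNko TGFB1 KO. It fell in both TGFB comparisons, with log2 fold changes of -1.82 ± 0.43, adjusted p = 0.0105 and -2.04 ± 0.43, adjusted p = 0.00556 (limma, Benjamini-Hochberg). A second Tgfb1 probe set had mean signals between 37.1 and 54.9 in the 4 groups and changed in none of the comparisons. The Ifng probe set had a mean signal of 18.4 ± 10.8 in wild type, 127 ± 64.5 in TGFB KO and 5.36 ± 3.72 in IFNko TGFB+. In the arrays labelled IFNko TGFB1 KO it was 60.9 ± 20.5, above its signal in IFNko TGFB+. The part of Ifng that was disrupted and the place of this probe set on the gene are not given in the sources used here, so this reading checks the label neither way, and the group is called by its label throughout.

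**Figure D1:**
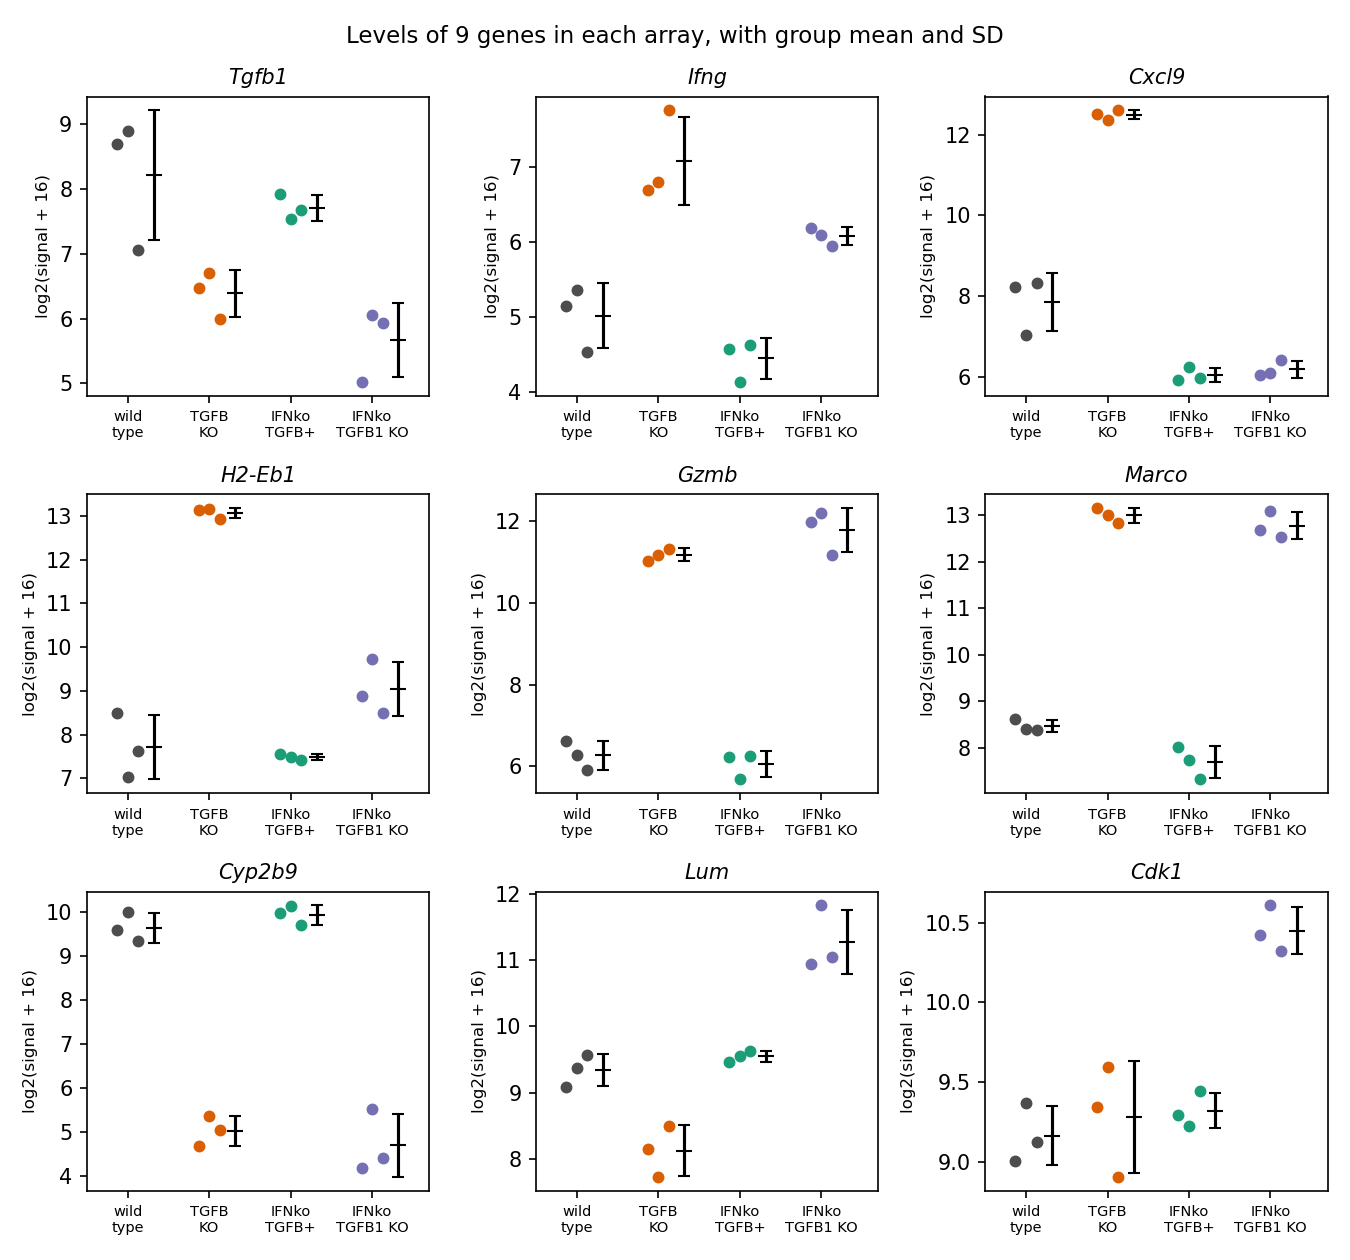
Levels of 9 genes in each of the 12 arrays, as log2(signal + 16) after quantile normalization on the y axis and the 4 groups on the x axis; points are arrays, and the bars give the mean and SD of 3 arrays. Cxcl9 lay between 12.4 and 12.6 in TGFB KO and between 6.05 and 6.42 in the arrays labelled IFNko TGFB1 KO, while Gzmb lay at 11.02 or above in both groups and Lum lay between 10.94 and 11.83 in the latter.

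TGFB KO against wild type asks what the loss of Tgfb1 changes where Ifng is intact. The lists of IFN-gamma inducible, antigen presentation, chemokine, Th1, T cell and macrophage genes rose, also with an estimated correlation (adjusted p between 0.0134 and 0.0451). Among single genes, Orm1, which encodes the acute phase plasma protein orosomucoid, rose by a log2 fold change of 7.27 ± 0.83, adjusted p = 0.000109, and Saa1, a serum amyloid, by 4.73 ± 0.58, adjusted p = 0.000175 (n = 3 arrays per group; limma, Benjamini-Hochberg). Ubd, an inducible ubiquitin-like modifier, rose by 5.89 ± 0.41, the chemokine gene Cxcl11 by 4.95 ± 0.46, and Acod1, which makes itaconate in activated macrophages, by 4.92 ± 0.47. The MHC class II genes H2-Eb1 and H2-Aa rose by 5.35 ± 0.36 and 4.73 ± 0.31. The killer cell protease gene Gzmb rose by 4.91 ± 0.28, Calhm6 by 4.75 ± 0.41 and the macrophage lectin gene Lgals3 by 4.73 ± 0.23. Of the 10 deepest falls, Cyp2b9 changed by -4.63 ± 0.33, adjusted p = 4.77e-06, Igfals, which encodes the acid-labile subunit that carries insulin-like growth factors in blood, by -4.28 ± 0.52, and the peroxisomal oxidase gene Hao2 by -3.95 ± 0.78. Cd209g (-3.61 ± 0.32), Ces1g (-3.36 ± 0.68), Ugt2a3 (-3.35 ± 0.39), Nrep (-3.24 ± 0.36), Keg1 (-3.21 ± 0.33) and Cyp2b10 (-3.20 ± 0.27) fell as well. Serpina6, the gene of corticosteroid-binding globulin, changed by -3.50 ± 0.95, adjusted p = 0.0199, but missed the threshold without wild type replicate 3, TGFB KO replicate 1 or TGFB KO replicate 3 (adjusted p between 0.0528 and 0.0739).

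Immune gene groups rose together in TGFB KO. All 24 tested IFN-gamma inducible genes rose, with a median log2 fold change of 2.72. Examples are the guanylate-binding protein genes Gbp2 (3.80 ± 0.18) and Gbp2b (4.19 ± 0.20), the transcription factor gene Irf8 (3.43 ± 0.21) and the chemokine gene Cxcl9 (4.64 ± 0.29). Of the 21 type I interferon stimulated genes 17 rose (median 1.73), among them Ifit2 (2.93 ± 0.13) and Oas1a (2.55 ± 0.27). Of 11 genes of MHC class I presentation 10 rose (median 1.65; 11 adjusted over the list alone), including the immunoproteasome gene Psmb8 (2.40 ± 0.21) and H2-K1 (2.13 ± 0.24). All 7 MHC class II presentation genes rose (median 4.53), as H2-Ab1 did by 4.53 ± 0.27. The chemokine and adhesion list had 16 of 17 members higher (Ccl5 3.75 ± 0.21, Cxcl10 2.98 ± 0.21). The Th1 and cytotoxic effector list had 16 of 18, or 18 adjusted over the list alone (Gzma 3.49 ± 0.33, Nkg7 2.30 ± 0.33). Among T cell markers 13 of 16 rose, such as Cd3g by 2.13 ± 0.28 and Cd3e by 2.09 ± 0.35. Markers of the Kupffer cell and macrophage list, called the macrophage list here, rose in 13 of 15 cases. Examples are the scavenger receptor gene Marco (4.52 ± 0.21) and the complement gene C1qb (2.64 ± 0.15). These 8 lists passed camera with adjusted p-values between 3.56e-28 and 2.91e-08, and also with an estimated correlation (adjusted p from 0.0134 to 0.0451). Their counts adjusted over the list alone were otherwise those over all genes.

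The neutrophil and monocyte, NK cell, acute phase, p53 and stress lists shifted up by camera, and lost the call with an estimated correlation. Neutrophil and monocyte markers rose in 14 of 20 cases, or 15 adjusted over the list alone, with Fpr2 at 3.74 ± 0.22, Il1b at 3.71 ± 0.26 and Ccr2 at 2.64 ± 0.20 (adjusted p = 0.188 with an estimated correlation). NK cell markers rose in 3 of 5 cases (4 adjusted over the list alone), including Klrk1 (2.12 ± 0.41; adjusted p = 0.101 with an estimated correlation). Acute phase genes rose in 8 of 20 cases, with Lcn2 at 4.23 ± 0.33 and Saa3 at 3.64 ± 0.34, and the other 12 did not pass (adjusted p = 0.276 with an estimated correlation). The p53 and cell death list had 7 of 14 members higher, or 8 adjusted over the list alone; the inflammatory caspase gene Casp1 (2.77 ± 0.26) and Pmaip1 (2.91 ± 0.33) led it (adjusted p = 0.104 with an estimated correlation). The list of endoplasmic reticulum and amino acid stress had 5 of 15 members higher (6 higher and 1 lower adjusted over the list alone), such as Atf3 (2.88 ± 0.34) and Ddit3 (1.77 ± 0.25; adjusted p = 0.0528 with an estimated correlation).

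Part of the genes of liver metabolism had lower RNA levels. Whole liver RNA does not tell lower expression per cell from a lower share of hepatocytes. Of 23 cytochrome P450 and conjugation genes 9 fell and 1 rose (median -0.81), with Ugt2b1 at -2.79 ± 0.49 and Gsta3 at -2.53 ± 0.47 (camera adjusted p = 0.000304; adjusted p = 0.491 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 17 cases (12 adjusted over the list alone) and rose in 2, with the regulator gene Ppara at -1.69 ± 0.32 and Acaa1b at -2.29 ± 0.26 (adjusted p = 0.356 with an estimated correlation). Lipid and cholesterol synthesis genes fell in 7 of 16 cases (8 adjusted over the list alone) and rose in 2; Srebf1, the transcription factor gene of this pathway, changed by -2.53 ± 0.29 and Fdft1 by -1.44 ± 0.20. That list had a camera adjusted p of 0.0124, which was 0.0717 without wild type replicate 3, and adjusted p = 0.129 with an estimated correlation. In the bile acid list, which did not pass as a whole (camera adjusted p = 0.0565, but 0.03 with the deposited scaling and 0.0109 under median centring), 7 of 17 genes fell and 1 rose (7 and 2 adjusted over the list alone). Among them were Nr0b2 (-1.38 ± 0.26) and the transporter gene Slco1a4 (-1.93 ± 0.40), while Baat, which conjugates bile acids, rose by 2.50 ± 0.37. The extracellular matrix and stellate cell list had 4 members higher and 3 lower of 18 (6 and 3 adjusted over the list alone), with a median of -0.062 and a mean of 0.19, and did not pass (camera adjusted p = 0.744). Vim (2.62 ± 0.23) and Timp1 (3.04 ± 0.44) rose there, and the stellate cell genes Reln (-1.98 ± 0.20) and Lrat (-1.14 ± 0.17) fell. Among 24 proliferation genes only Top2a passed, at 0.60 ± 0.20, adjusted p = 0.0495, with 0 adjusted over the list alone, and it missed the threshold without wild type replicate 1 or 2 or TGFB KO replicate 1 or 2 (0.157, 0.101, 0.166 and 0.122). The lists of TGF-beta targets, hepatocyte, erythroid, B and plasma cell, endothelial, cholangiocyte, dendritic, megakaryocyte and mast cell, fetal hepatocyte, urea cycle, gluconeogenesis, Th2 and Th17, and of pancreas, intestine and adipose genes did not pass (camera adjusted p of at least 0.0699). Of these the hepatocyte list, at a median of -0.32, passed with the deposited scaling (-0.47, adjusted p = 0.00939) and under median centring (-0.40, adjusted p = 0.013). The megakaryocyte and mast cell list passed without wild type replicate 1 or TGFB KO replicate 3 (0.0329 and 0.0333), the endothelial list without TGFB KO replicate 3 (0.0175), and the dendritic list by fry (0.0471).

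Across 12755 tested genes, 1553 were higher and 1524 lower in TGFB KO (limma, adjusted p under 0.05), and 1075 and 717 of these by at least 2-fold. With the arrays centred on their medians the split was 1449 higher and 894 lower, and an ordinary t statistic called 1938 genes. Of the 114 named genes past the threshold, 17 missed it with 1 array left out.

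IFNko TGFB1 KO against IFNko TGFB+ asks the same question in mice labelled as lacking Ifng. The arrays labelled IFNko TGFB1 KO, in which the Ifng probe set still gave signal (log2 fold change 1.63 ± 0.30, adjusted p = 0.00243, limma, Benjamini-Hochberg), had higher levels of the T cell and the Th1 and cytotoxic effector lists, also with an estimated correlation (adjusted p = 0.0213 and 0.0307). Gzmb rose by 5.73 ± 0.28, adjusted p = 5.49e-07, and Trav9d-3, a variable segment of the T cell receptor alpha chain, by 4.72 ± 0.21 (n = 3 arrays per group; limma). The chemokine genes Ccl5, Ccl8 and Ccl6 rose by 4.85 ± 0.21, 4.63 ± 0.58 and 4.34 ± 0.35, Marco by 5.08 ± 0.21 and Lgals3 by 4.47 ± 0.23. S100a4 (5.30 ± 0.46), Ms4a4b (4.92 ± 0.28) and Orm1 (4.58 ± 0.83) complete the 10 largest rises. The deepest falls were those of Cyp2b9 (-5.25 ± 0.33, adjusted p = 5.38e-06), Cyp1a2 (-4.44 ± 0.78), Serpina6 (-4.27 ± 0.95), Sult2a8 (-4.13 ± 0.57) and Cyp4f14 (-4.05 ± 0.47). Inmt (-3.85 ± 0.84), Thrsp (-3.77 ± 0.38), the tryptophan dioxygenase gene Tdo2 (-3.75 ± 0.58), Ces1g (-3.73 ± 0.68) and Ugt2a3 (-3.70 ± 0.39) followed. These 20 genes kept their call with each array left out.

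All 16 T cell markers rose (median 2.19), among them Cd3g (4.14 ± 0.28), Cd3d (4.32 ± 0.39) and the CD8 beta chain gene Cd8b1 (3.14 ± 0.30). So did 17 of 18 Th1 and cytotoxic effector genes (median 2.08), with Gzma at 4.19 ± 0.33 and Cxcr6 at 3.65 ± 0.30. Ifng itself is among these 17. These lists passed camera (adjusted p = 4.93e-14 and 5.51e-14), and also with an estimated correlation (adjusted p = 0.0213 and 0.0307). Macrophage markers rose in 14 of 15 cases, such as Cd5l by 3.64 ± 0.18 (camera adjusted p = 1.69e-15; adjusted p = 0.0539 with an estimated correlation). Chemokine and adhesion genes rose in 15 of 17 cases, or 16 adjusted over the list alone, with Vcam1 at 2.64 ± 0.25 (camera adjusted p = 6.32e-13; adjusted p = 0.0539 with an estimated correlation). Neutrophil and monocyte markers rose in 16 of 20, or 18 adjusted over the list alone (Ccr2 2.99 ± 0.20, Cd14 3.21 ± 0.38), with adjusted p = 0.276 with an estimated correlation. NK cell markers rose in 3 of 5, or 4 over the list alone (Klrd1 2.15 ± 0.23), with adjusted p = 0.0815 with an estimated correlation. MHC class II genes rose in 6 of 7 cases (median 1.77; H2-Ab1 1.77 ± 0.27), with adjusted p = 0.285 with an estimated correlation. MHC class I presentation genes rose in 4 of 11, or 5 adjusted over the list alone (H2-K1 1.68 ± 0.24), with adjusted p = 0.321 with an estimated correlation. The 24 IFN-gamma inducible genes went both ways, 8 higher, such as Irf8 (1.48 ± 0.21), and 5 lower, such as the GTPase genes Irgm1 (-1.27 ± 0.16) and Irgm2 (-1.60 ± 0.21). Adjusted over the list alone these were 11 and 5. The list did not pass camera (adjusted p = 0.0706), but did by fry (0.0424) and with no filter on dim probe sets (0.0378). The type I interferon list had 4 higher and 3 lower of 21 (6 and 5 over the list alone) and did not pass either (camera adjusted p = 0.581).

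Proliferation genes rose in 20 of 24 cases, or 22 adjusted over the list alone, with a median of 0.81. Cdc20 (1.37 ± 0.21), the cyclin gene Ccnb2 (0.98 ± 0.16) and Cdk1 (1.13 ± 0.20) are examples (camera adjusted p = 3.74e-09; adjusted p = 0.136 with an estimated correlation). Extracellular matrix and stellate cell genes rose in 10 of 18 cases, or 14 adjusted over the list alone (median 0.95), among them the collagen gene Col5a2 (1.45 ± 0.18), Pdgfra (1.72 ± 0.21) and Timp1 (3.17 ± 0.44; adjusted p = 0.223 with an estimated correlation). The p53 and cell death list (5 higher and 1 lower of 14; 7 and 2 adjusted over the list alone) and the megakaryocyte and mast cell list (2 higher of 8) passed at an adjusted p of 0.0452 each. Both missed it without IFNko TGFB1 KO replicate 2, at 0.112 and 0.168, and had adjusted p = 0.344 and adjusted p = 0.437 with an estimated correlation. The p53 list also missed it without IFNko TGFB+ replicate 1 or IFNko TGFB1 KO replicate 3, and the megakaryocyte list without IFNko TGFB+ replicate 2 or IFNko TGFB1 KO replicate 3 (adjusted p between 0.0628 and 0.0952). The acute phase, stress response, TGF-beta target, Th2 and Th17, dendritic, erythroid, B and plasma cell, endothelial, cholangiocyte, fetal hepatocyte, and pancreas, intestine and adipose lists did not pass (camera adjusted p of at least 0.0574). Without IFNko TGFB1 KO replicate 1 the B and plasma cell, erythroid and endothelial lists passed (0.0349, 0.0349 and 0.0439), and the endothelial list also without IFNko TGFB+ replicate 2 or IFNko TGFB1 KO replicate 3 (0.0467 and 0.0337). By fry the dendritic (0.00833), Th2 and Th17 (0.0253), stress response, TGF-beta target and endothelial lists (0.0424 each) passed as well.

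Cytochrome P450 and conjugation genes fell in 16 of 23 cases, or 17 adjusted over the list alone (median -1.86), with Cyp2b10 at -2.73 ± 0.27 and Cyp2f2 at -2.44 ± 0.25. Bile acid genes fell in 10 of 17 and rose in 1 (12 lower adjusted over the list alone), with the nuclear receptor gene Nr1h4 at -1.75 ± 0.20 and Slco1a4 at -3.07 ± 0.40. Urea cycle and amino acid catabolism genes fell in 10 of 16 (Hal -1.89 ± 0.24, Fah -1.88 ± 0.33). Fatty acid oxidation genes fell in 10 of 17 with 2 higher, or 13 lower adjusted over the list alone (Ppara -2.12 ± 0.32, Pdk4 1.59 ± 0.29). Lipid and cholesterol synthesis genes fell in 7 of 16 with 2 higher, or 10 lower over the list alone (Hmgcs1 -1.69 ± 0.21, Srebf1 -1.73 ± 0.29). Hepatocyte markers fell in 8 of 18, or 11 adjusted over the list alone (Cebpa -1.61 ± 0.30, F9 -1.23 ± 0.23). These 6 lists passed camera (adjusted p between 2.2e-09 and 0.00195), and with an estimated correlation their adjusted p-values lay between 0.121 and 0.389. The gluconeogenesis and glycogen list had 4 of 12 genes lower (5 lower and 1 higher adjusted over the list alone), including Gpt (-2.49 ± 0.35). Its camera adjusted p was 0.0263, and 0.16 without IFNko TGFB1 KO replicate 2, and adjusted p = 0.476 with an estimated correlation. The array of that replicate had a mean log2 level of 8.16 over the cytochrome P450 list, against 9.57 and 9.77 in the other arrays of its group. Over the hepatocyte list its mean was 12.2, against 12.8 and 12.9.

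Of the 12755 genes, 1619 were higher and 1673 lower (limma, adjusted p under 0.05), 972 and 925 of them by at least 2-fold. Centring on array medians shifted the median of all genes by -0.144 on the log2 scale, and then 988 genes were higher and 1866 lower. An ordinary t statistic called 1352 (851 higher and 501 lower). With 1 array left out, 13 of the 117 named genes past the threshold missed it.

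**Figure D2:**
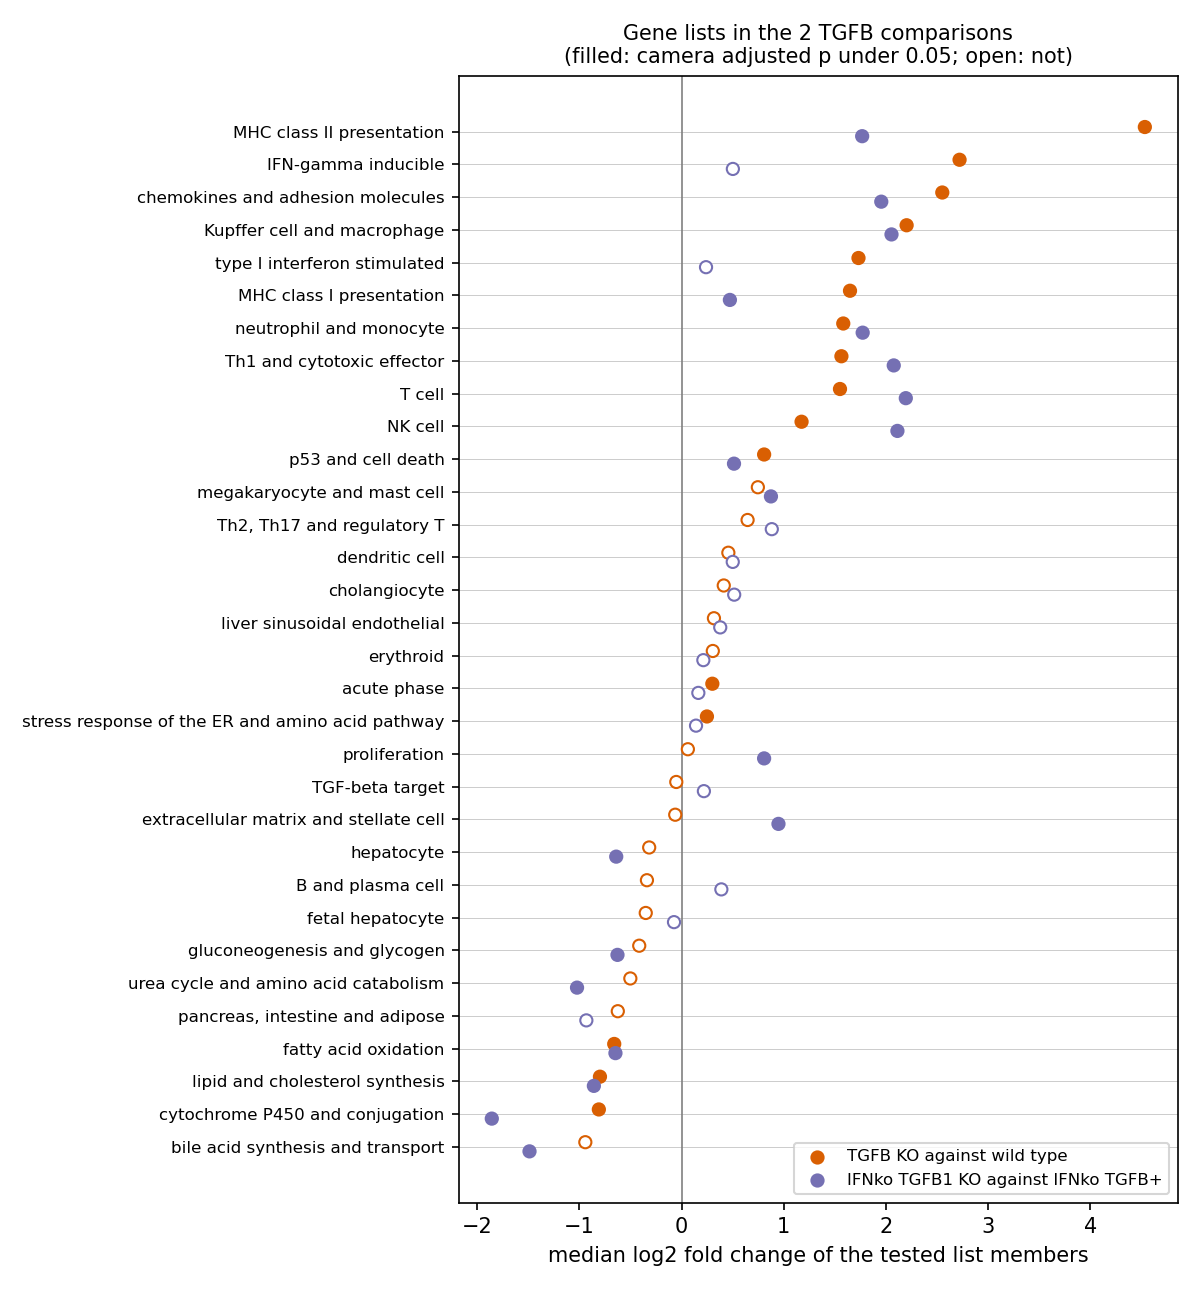
Median log2 fold change of the tested members of each of 32 gene lists on the x axis, in TGFB KO against wild type and in IFNko TGFB1 KO against IFNko TGFB+; filled points passed camera at an adjusted p under 0.05. The IFN-gamma inducible list lies at 2.72 in the first and 0.50 in the second, while the T cell list lies at 1.55 and 2.19.

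The difference of the TGFB effects compares the fold change between the arrays labelled IFNko TGFB1 KO and IFNko TGFB+ with that between TGFB KO and wild type, and so asks which changes depend on Ifng. The lists of IFN-gamma inducible, MHC class I and MHC class II genes rose less in the mice labelled IFNko, also with an estimated correlation (adjusted p = 0.00192, 0.0296 and 0.0437). Of 18 matrix and stellate cell genes 6 had a higher difference, and that list had adjusted p = 0.166 with an estimated correlation. Cxcl9 had a difference of -4.50 ± 0.42, adjusted p = 0.00037 on the log2 scale (limma, Benjamini-Hochberg; n = 3 arrays in each of 4 groups). The collagenase gene Mmp13 had -4.50 ± 0.65, Acod1 -4.32 ± 0.66, Cxcl11 -4.16 ± 0.65, H2-Eb1 -3.79 ± 0.50 and Ubd -3.77 ± 0.58. On the other side, Il13ra2, which encodes a decoy receptor for interleukin 13, had a difference of 3.14 ± 0.43, adjusted p = 0.0064. The matrix proteoglycan gene Lum had 2.94 ± 0.37, the matricellular gene Postn 2.34 ± 0.32 and Reln 2.31 ± 0.29. Ly6d had 2.59 ± 0.47, adjusted p = 0.0261, but missed the threshold when any of 8 single arrays was left out (adjusted p between 0.0506 and 0.0783). Cd209f had 2.36 ± 0.41, adjusted p = 0.0216, and missed it without TGFB KO replicate 3, IFNko TGFB+ replicate 2 or IFNko TGFB+ replicate 3 (0.0606 to 0.074).

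All 24 tested IFN-gamma inducible genes had a negative difference when adjusted over the list alone, and 18 over all genes, with a median of -2.32 (Gbp2 -3.42 ± 0.26, Igtp -3.72 ± 0.30). Type I interferon stimulated genes were lower in 7 of 21 cases, or 15 adjusted over the list alone (Ifit2 -2.55 ± 0.19). MHC class II genes were lower in 4 of 7, or 7 over the list alone (H2-Ab1 -2.77 ± 0.38). MHC class I presentation genes were lower in 2 of 11, or 9 over the list alone (Psmb8 -1.36 ± 0.29, adjusted p = 0.063 over all genes). T cell markers had a median difference of 1.13, with 1 of 16 past the threshold over all genes and 5 higher adjusted over the list alone. These 5 lists passed camera (adjusted p between 3.63e-49 and 1.3e-08), also with an estimated correlation (adjusted p from 0.00192 to 0.0437). The extracellular matrix and stellate cell list was higher in 6 of 18 genes, or 9 adjusted over the list alone (median 0.89; Lrat 2.19 ± 0.25), with a camera adjusted p of 1.97e-09 and adjusted p = 0.166 with an estimated correlation. No proliferation gene passed over all genes and 10 of 24 did adjusted over the list alone (median 0.74; camera adjusted p = 2.21e-12; adjusted p = 0.0629 with an estimated correlation). The Th1 and cytotoxic effector (0.70), acute phase (-0.54), urea cycle (-0.76), stress response (-0.48) and p53 (-0.33) lists passed camera by their medians too, and with an estimated correlation had adjusted p = 0.286, 0.34, 0.408, 0.0578 and 0.34. The p53 list missed the threshold without wild type replicate 1, TGFB KO replicate 3, IFNko TGFB+ replicate 2 or IFNko TGFB1 KO replicate 3 (adjusted p between 0.0549 and 0.0758). The macrophage, neutrophil and monocyte, fatty acid oxidation, and lipid and cholesterol synthesis lists did not pass for the difference (camera adjusted p = 0.781 each). Lists that missed the threshold in the main analysis, but passed with a single array left out, were chemokine (0.046) and erythroid (0.0249) without IFNko TGFB1 KO replicate 2, NK cell without wild type replicate 2 (0.0359), and gluconeogenesis without IFNko TGFB1 KO replicate 1 or 3 (0.0468 and 0.0402). With all arrays the NK cell list passed under median centring (0.0213) and the gluconeogenesis list with the deposited scaling (0.0472). The fetal hepatocyte list (camera adjusted p = 0.0531) passed without wild type replicate 2 or 3, TGFB KO replicate 1, IFNko TGFB+ replicate 3 or IFNko TGFB1 KO replicate 2 (0.0103 to 0.0468). The cytochrome P450 (-0.48), bile acid (-0.78), hepatocyte (-0.37) and B and plasma cell (0.51) lists had median differences that passed camera with all arrays. Without IFNko TGFB1 KO replicate 2 their adjusted p-values were 0.58, 0.122, 0.534 and 0.41, and with an estimated correlation adjusted p was at least 0.486. The B and plasma cell list also missed it without wild type replicate 1, TGFB KO replicate 3 or IFNko TGFB+ replicate 2 (0.127, 0.104 and 0.0659).

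Across the 12755 genes the fold changes of these TGFB comparisons, which share no arrays, had a Pearson r of 0.732 and a Spearman rho of 0.668; genes are not independent replicates. There were 957 genes higher in both, where independent lists of these sizes would share 197, and 962 lower in both, against 200. Of 1933 genes past the threshold in both, 14 had opposite directions. A difference of effects passed the test for 111 genes, 31 higher and 80 lower, among them 55 of the 1144 genes called in TGFB KO alone and 17 of the 1359 called in IFNko TGFB1 KO alone. Centring on array medians shifted the median difference of all genes by -0.262 and gave 9 higher and 101 lower. A pseudocount of 1 gave 57 genes, a pseudocount of 64 gave 212 and an intensity trend 173. The count of 111 was 68 without wild type replicate 2, 63, 73 and 73 without TGFB KO replicates 1, 2 and 3, and 64, 46 and 61 without IFNko TGFB+ replicates 1, 2 and 3. For this difference, 13 of the 34 named genes past the threshold missed it with 1 array left out.

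**Figure D3:**
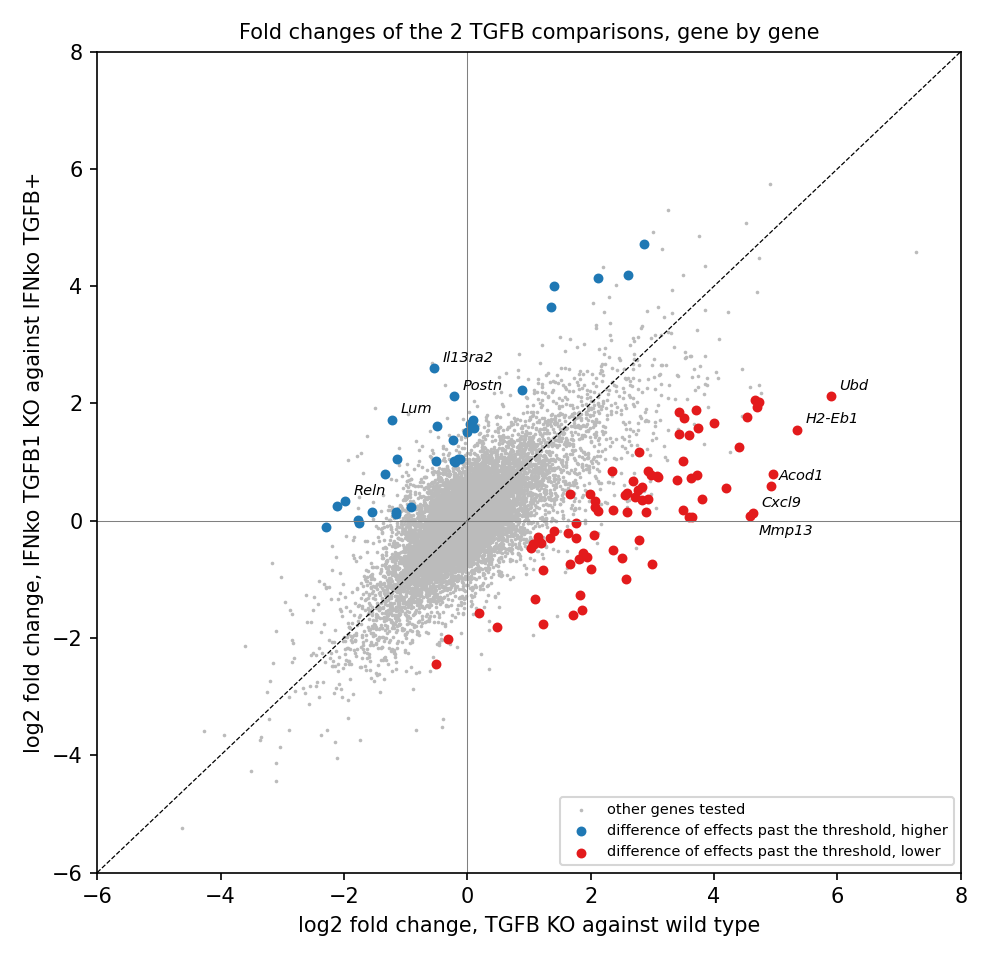
Log2 fold change of each of 12755 genes in TGFB KO against wild type (x axis) and in IFNko TGFB1 KO against IFNko TGFB+ (y axis); the dashed line marks equal changes, and coloured points are the 31 genes with a higher and the 80 with a lower difference of effects past the threshold. Ubd, Cxcl9, Acod1, Mmp13 and H2-Eb1 lie below the line, and Lum, Reln, Il13ra2 and Postn above it.

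IFNko TGFB1 KO against TGFB KO asks how the livers without Tgfb1 differ by the Ifng label. The IFN-gamma inducible list was lower in the arrays labelled IFNko TGFB1 KO and the T cell and proliferation lists higher, also with an estimated correlation (adjusted p = 0.00171, 0.014 and 0.0346). Of 18 matrix and stellate cell genes 9 rose, and that list had adjusted p = 0.245 with an estimated correlation. Cxcl9 changed by -6.30 ± 0.29, adjusted p = 5.95e-07 (limma, Benjamini-Hochberg; n = 3 arrays per group). Acod1 changed by -5.08 ± 0.47, Ubd by -5.05 ± 0.41, Mmp13 by -4.49 ± 0.46, Gbp2b by -4.30 ± 0.20 and the GTPase gene Igtp by -4.28 ± 0.21. The Ifng probe set itself was at -1.005 ± 0.30, adjusted p = 0.0783, which did not pass. Lum rose by 3.15 ± 0.26, adjusted p = 5.59e-05, Ly6d by 2.81 ± 0.33, Cd209f by 2.56 ± 0.29, Postn by 2.35 ± 0.23 and Il13ra2 by 2.32 ± 0.31. Retnla, a gene induced in macrophages by interleukin 4, rose by 2.87 ± 0.68, adjusted p = 0.0343, and missed the threshold without TGFB KO replicate 1, 2 or 3 (adjusted p between 0.0887 and 0.0955).

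Of 24 IFN-gamma inducible genes 23 fell (24 adjusted over the list alone; median -3.10). So did 15 of 21 type I interferon stimulated genes (18 over the list alone; Ifit2 -2.57 ± 0.13), all 11 MHC class I presentation genes (Tap1 -3.01 ± 0.33) and 6 of 7 MHC class II genes (7 over the list alone; H2-Eb1 -4.02 ± 0.36). T cell markers rose in 8 of 16 cases, or 14 adjusted over the list alone (Cd2 2.12 ± 0.28, Zap70 1.12 ± 0.21). Proliferation genes rose in 15 of 24, or 23 over the list alone (Ccnb2 1.18 ± 0.16, Bub1b 0.95 ± 0.18). These 6 lists passed camera (adjusted p between 9.91e-51 and 7.49e-11), also with an estimated correlation (adjusted p from 0.00171 to 0.0346). Extracellular matrix and stellate cell genes rose in 9 of 18 cases, or 11 adjusted over the list alone with 1 lower (Lrat 2.04 ± 0.17, Reln 2.16 ± 0.20), with a camera adjusted p of 4.44e-07 and adjusted p = 0.245 with an estimated correlation. Both Lrat and Reln had fallen in TGFB KO against wild type. The Th1 and cytotoxic effector list had 5 higher and 1 lower of 18, or 9 and 3 adjusted over the list alone (Cxcr6 2.15 ± 0.30; adjusted p = 0.245 with an estimated correlation). The acute phase list had 1 higher and 4 lower of 20, or 1 and 11 over the list alone (adjusted p = 0.245 with an estimated correlation). The stress response list had 2 of 15 and the p53 list 1 of 14 genes lower (adjusted p = 0.0543 and 0.293 with an estimated correlation), and the p53 list missed the camera threshold without TGFB KO replicate 3 (0.0642). The chemokine and macrophage lists, which did not pass (camera adjusted p = 0.145 and 0.286), were lower with the deposited scaling (0.0471 and 0.0082) and without IFNko TGFB1 KO replicate 2 (0.0221 and 0.0404). The chemokine list had a median of -0.24 with 3 of 17 members lower, or 4 higher and 5 lower adjusted over the list alone. The macrophage list was also lower under median centring (0.0409), and the chemokine list with arrayWeights (0.032) and by fry (0.024). In the neutrophil and monocyte list, which did not pass, Fpr2 (-1.86 ± 0.22) and Il1b (-1.52 ± 0.26) fell. The cytochrome P450 list had a median of -0.46 with 3 of 23 genes lower, among them Cyp2f2 (-1.71 ± 0.25), and a camera adjusted p of 0.00171. Without IFNko TGFB1 KO replicate 2, the array with the lowest level of that list, its median was 0.0996 with an adjusted p of 0.916. The bile acid, urea cycle, hepatocyte, and B and plasma cell lists likewise passed with all arrays and not without that replicate (adjusted p = 0.109, 0.107, 0.402 and 0.347), and the B and plasma cell list not without TGFB KO replicate 3 (0.093). With an estimated correlation adjusted p was 0.637 for the cytochrome P450, 0.462 for the bile acid, 0.468 for the urea cycle, 0.554 for the hepatocyte and 0.629 for the B and plasma cell list.

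In all, 324 genes were higher and 360 lower (limma, adjusted p under 0.05), 166 and 271 of them by at least 2-fold. The 684 genes were 327 and 363 without TGFB KO replicates 1 and 2, 416 without IFNko TGFB1 KO replicate 1, and 421 (175 higher and 246 lower) when all steps were repeated without the latter, the array that stood apart. Centring on array medians shifted the median of all genes by -0.162 and gave 100 higher and 388 lower, and a fit of these groups alone called 213. An ordinary t statistic called 27 (4 higher and 23 lower). Here 27 of the 75 named genes past the threshold missed it with 1 array left out. Because both comparisons use the TGFB KO arrays, the covariance of these fold changes with those of TGFB KO against wild type is negative by construction. It was -0.167, against -0.053 in simulated groups with no effect, a difference of -0.114. Of the 1553 genes higher in TGFB KO than in wild type 272 were lower here, where independent lists would share 43.8. Simulated groups with no effect shared a mean of 0.01 calls in either direction, but hold no TGFB effect, so part of that excess may still come from the shared arrays.

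IFNko TGFB+ against wild type asks what the Ifng label changes where Tgfb1 is present. No gene passed the threshold (limma, Benjamini-Hochberg; n = 3 arrays per group), with a smallest adjusted p of 0.373 and 649 of 12755 genes at an unadjusted p under 0.05. An ordinary t statistic called 0 as well, while 2 genes passed without wild type replicate 2, 2 without wild type replicate 3 and 1 without IFNko TGFB+ replicate 1. Cxcl9 had a log2 fold change of -1.80 ± 0.29, adjusted p = 0.398, Socs1 -1.01 ± 0.27 and Gbp2 -0.63 ± 0.18. The IFN-gamma inducible list had a median of -0.50 and a lower shift by camera (adjusted p = 1.04e-12), with 6 of its 24 genes lower adjusted over the list alone and adjusted p = 0.151 with an estimated correlation, but 0.0452 by fry. MHC class I presentation genes had a median of -0.55 (camera adjusted p = 1.38e-06; adjusted p = 0.151 with an estimated correlation and 0.0676 by fry), with H2-K1 at -1.02 ± 0.24 and 1 of 11 lower adjusted over the list alone. The 6 fetal hepatocyte genes had a median of -0.56 at a camera adjusted p of 0.032, which was 0.348 without wild type replicate 1, 0.138 without IFNko TGFB+ replicate 2, 0.609 by fry, and adjusted p = 0.653 with an estimated correlation. The other 29 lists did not pass (camera adjusted p of at least 0.077). Without wild type replicate 2 the MHC class II (0.0133), chemokine (0.048), proliferation (0.0274) and macrophage (0.000657) lists did, and without IFNko TGFB+ replicate 1 the chemokine (0.0273) and macrophage (0.0484) lists.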

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

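Of the tests in this part, the levels of the IFN-gamma inducible list as a check for exchanged labels, the reading of the Ifng probe set, the comparison with endothelial and cholangiocyte markers and the use of the estimated correlation, itself a planned test, to weigh chance in the last pattern were chosen after the result was seen, and the steps repeated without IFNko TGFB1 KO replicate 1 and the list for interleukin 4 and interleukin 13 after the data were seen. The difference of the TGFB effects was itself tested with limma, and it passed for 31 genes with a higher and 80 with a lower log2 fold change in IFNko TGFB1 KO against IFNko TGFB+ than in TGFB KO against wild type. Among named genes the log2 differences were -4.50 for Mmp13, -4.50 for Cxcl9, -4.32 for Acod1, -4.16 for Cxcl11, -3.79 for H2-Eb1, -3.77 for Ubd and -2.71 for H2-Aa, which missed the threshold without IFNko TGFB+ replicate 2 (adjusted p = 0.056 in limma). They were 3.14 for Il13ra2, 2.94 for Lum, 2.59 for Ly6d, 2.36 for Cd209f, 2.34 for Postn, 2.31 for Reln and 1.85 for Trav9d-3. By camera, lists with a lower median difference were IFN-gamma inducible (-2.32), type I interferon stimulated (-1.51), MHC class I presentation (-1.03), MHC class II presentation (-2.77), acute phase (-0.54), cytochrome P450 (-0.48), bile acid (-0.78), urea cycle (-0.76), p53 (-0.33), stress response (-0.48) and hepatocyte (-0.37). Lists with a higher one were Th1 and cytotoxic effector (0.70), proliferation (0.74), extracellular matrix and stellate cell (0.89), T cell (1.13), and B and plasma cell (0.51). Of these lists the IFN-gamma inducible, type I interferon, MHC class I, MHC class II and T cell lists alone passed with an estimated correlation as well. The cytochrome P450, bile acid, hepatocyte, and B and plasma cell lists did not pass without IFNko TGFB1 KO replicate 2. Among 4076 probe sets with no or several symbols, which the comparisons do not use, limma called 379 in TGFB KO against wild type and 364 in IFNko TGFB1 KO against IFNko TGFB+.

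The Ifng probe set gave more signal in the arrays labelled IFNko TGFB1 KO than in IFNko TGFB+. If these mice had an intact Ifng gene, their IFN-gamma inducible genes would be near the level of TGFB KO, but the highest of these arrays lay 2.96 below the lowest TGFB KO array in the mean log2 of the list, against an SD of 0.113 between arrays. RNA of TGFB KO liver mixed into the samples would carry all transcripts in the same share, but the median share of the TGFB KO excess held by the IFN-gamma inducible genes was 3.46 percent (upper quartile 7.92), against 37.5 percent for Ifng. A candidate explanation that stays open is that the probe set reads a transcript still made from the disrupted gene, since the rise of 1.63 cannot be told apart from other sources without the place of the probe set on the gene.

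Of 18 extracellular matrix and stellate cell genes 9 were higher in the arrays labelled IFNko TGFB1 KO than in TGFB KO, and the list passed camera and fry (0.00203) but not camera with an estimated correlation (adjusted p = 0.245, limma). A lower share of hepatocytes alone would raise markers of the other liver cells alike. Endothelial and cholangiocyte markers had a mean change of -0.0867, which lay -0.91 (SE 0.268) from that of the list. This SE takes genes as independent, though those of the matrix and endothelial lists varied together (estimated correlations 0.402 and 0.357). The hepatocyte list passed as lower with all arrays (camera adjusted p = 0.00356), but not without IFNko TGFB1 KO replicate 2. A lower share of hepatocytes was thus not excluded as a part of the pattern. Neither IFNko TGFB1 KO replicate 1 nor 2 alone accounts for the pattern, as the list had a median of 0.86 with all steps repeated without replicate 1 (list mean 10.19), and of 0.55 (camera adjusted p = 0.00027) without replicate 2, which had the highest list mean (10.86, against 10.04 in replicate 3) and the lowest hepatocyte mean (12.23). A response to interleukin 4 and interleukin 13 might be behind it, and stays open: a separate list of 19 such genes, 14 of them tested, had a median of 0.0572 with members that went both ways (Chil4 higher, Ccl24 and Pdcd1lg2 lower). More stellate cells or more matrix expression per cell remain open as well and were not tested. For Reln and Lrat, part of the difference is their fall in TGFB KO against wild type, where 4 of the 18 genes rose and 3 fell. For Reln that fall, at -1.98, is most of its difference of the TGFB effects of 2.31. Lum also lay lower in TGFB KO (7.73 to 8.49) than in wild type (9.09 to 9.56). It lay above both in the arrays labelled IFNko TGFB1 KO (10.94 to 11.83).

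The IFN-gamma inducible list was lower in IFNko TGFB+ than in wild type, with list means of 7.51 to 7.61 in the IFNko TGFB+ arrays and 7.88 to 8.27 in the wild type arrays. A single wild type array is not the source, as the median nearest 0 with any of these left out was -0.41 (-0.409). Scaling is not either, as the median nearest 0 under another scaling was -0.40 (-0.398). By camera with an estimated correlation, which sets the list against the other genes, the adjusted p was 0.151. By fry, which tests the list against no change and also allows for genes that vary together, it was 0.0452. These tests ask different questions, and the list passed fry only narrowly. A chance difference between mice in genes that vary together is therefore not excluded as an alternative to an effect of the Ifng label.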

How the results depend on the processing

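In this part, the steps repeated without the array IFNko TGFB1 KO 1 and the covariates for sex and for the Gapdh ratio were chosen after the data were seen. Of 340 named gene values past the threshold, 243 stayed past it in the same direction under all alternatives run for them, while 70 missed it without some array and 87 under another alternative. Of 70 list shifts, 54 stayed past it in all but the estimated correlation and fry, under which 49 and 16 missed it; 16 missed it without some array and 5 under another alternative. Of the 90 list shifts not past it, 16 came past it without some array and 29 under another alternative, fry included. With the Gapdh ratio as a covariate, 24 named gene values and 3 list shifts missed it. The counts were then 3030, 2817, 116, 593 and 0 in the order of the contrasts. The log2 Gapdh ratio was -0.419 to -0.162 in IFNko TGFB1 KO and -0.617 to -0.577 in IFNko TGFB+. The same ratio for the Actb control was 0.691 to 0.813 and 1.03 to 1.17, against 0.408 to 0.63 in TGFB KO. These ratios and the group labels thus cannot be fully told apart. The cytochrome P450 list in IFNko TGFB1 KO against TGFB KO changed sign without IFNko TGFB1 KO replicate 2, where its median was 0.0996 (range with single arrays left out -0.72 to 0.0996); the cause was not tested.

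With a threshold of 2-fold added, 1792, 1897 and 437 genes were left in TGFB KO against wild type, IFNko TGFB1 KO against IFNko TGFB+ and IFNko TGFB1 KO against TGFB KO, by construction, against 3077, 3292 and 684. An ordinary t statistic, which shares the spread neither between genes nor with the arrays of other groups, gave 1938, 1352 and 27. For IFNko TGFB1 KO against TGFB KO, fitting only these 6 arrays gave 213 and repeating all steps with 11 arrays 421, each with fewer arrays. The 111 genes with a difference of effects became 57 with a pseudocount of 1, 212 with 64 and 173 with an intensity trend; the cause was not tested. The correlation of the TGFB effects, 0.732, was 0.69 and 0.761 with these pseudocounts, 0.659 without a filter and 0.785 with a filter at the 60th percentile, against an SD of 0.017 over arrays left out; the cause was not tested. With each array left out in turn the counts ranged from 2200 to 2580 for TGFB KO against wild type, 2261 to 3535 for IFNko TGFB1 KO against IFNko TGFB+, 46 to 160 for the difference of effects, 327 to 730 for IFNko TGFB1 KO against TGFB KO, and 0 to 2 for IFNko TGFB+ against wild type. The correlation ranged from 0.685 to 0.745, the genes higher in both from 781 to 964 and those lower in both from 663 to 1060.

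The groups share replicate numbers, which were not taken to pair the samples, since the sources used here do not say what a number marks. Of the 6 pairs of arrays with the same number, 0, 1 and 3 had deviations that correlated above 0.1 for numbers 1, 2 and 3, and 6 of 12 arrays correlated best with an array of their own number. The highest of these correlations was 0.34, for number 3. Arrays of unlike numbers were not counted in the same way, so these counts do not settle whether the numbers pair the samples. With the number as a replicate block the counts were 3051, 3277, 84, 571 and 0. Under the block 20 named gene values were no longer past the threshold and 6 came past it; of lists, the megakaryocyte list in IFNko TGFB1 KO against IFNko TGFB+ (adjusted p = 0.0505 by camera) and the fetal hepatocyte list in IFNko TGFB+ against wild type (0.0521) missed it, and the fetal hepatocyte list passed for the difference of effects (0.0424). Dim genes lie near the background, where the pseudocount sets their fold changes.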

Other observations

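In this part, the choice of gene families was made after the results were seen, and the splits of the arrays and the neighbours of the targeted genes were planned before. Families of genes that share a symbol stem were tested for an excess of calls (211 families of at least 8 genes, one-sided Fisher test, Benjamini-Hochberg; limma calls from 3 arrays per group). The Fisher test takes genes as independent, though related genes may vary together between mice. In the cytochrome P450 list, for example, the estimated correlation was 0.579. The Fisher p-values can therefore be too small and only describe the counts. Carboxylesterase genes (Ces), which cleave esters of drugs and lipids, fell in 6 of 11 cases in TGFB KO against wild type and in 9 in IFNko TGFB1 KO against IFNko TGFB+ (Fisher adjusted p = 0.0411 and 5.1e-05). Ces1e fell by 1.98 ± 0.46 and 2.44 ± 0.46 on the log2 scale, and Ces1f by 1.56 ± 0.34 and 2.67 ± 0.34. Hydroxysteroid dehydrogenase genes (Hsd) fell in 9 and 7 of 13 (0.000467 and 0.0232), with Hsd3b2 at -2.21 ± 0.32 and -2.25 ± 0.32. Genes of peroxisome assembly (Pex) fell in 7 and 8 of 13 (0.0215 and 0.00317), with Pex7 at -1.27 ± 0.25 and -1.13 ± 0.25, while Pex11a rose in the first by 0.60 ± 0.19. The medians of these 3 families were negative in both comparisons under each scaling, and under median centring 3 Pex genes fell in the first and none rose.

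Lymphocyte GTPase genes (Gimap) rose in 5 of 8 cases in each of these comparisons (Fisher adjusted p = 0.0254 and 0.0347), with Gimap4 at 1.26 ± 0.16 and 2.18 ± 0.16 and Gimap7 at 2.31 ± 0.36 and 3.37 ± 0.36. Genes of the Ms4a membrane proteins rose in 8 of 11 in each (0.000294 and 0.000539), with Ms4a6d at 4.08 ± 0.24 and 3.10 ± 0.24 and Ms4a7 at 1.51 ± 0.30 and 2.60 ± 0.30. The medians of these families were positive under each scaling. Genes with the symbol stems Rpl and Rps rose in 11 of 23 and 12 of 25 cases (the latter stem also takes in kinase genes such as Rps6ka3, which is among the 12) in IFNko TGFB1 KO against IFNko TGFB+, but in 4 and 7 with the deposited scaling and in 1 and 1 under median centring, where their medians were 0.14 and 0.17.

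The 6 arrays of a comparison split into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. Any other split puts a real difference between the groups into the spread within its groups, which lowers its count. The counts of other splits therefore do not measure chance. For TGFB KO against wild type the real split, with 3077 genes, was the 1 split of 10 with as many, and the highest other gave 0. For IFNko TGFB1 KO against IFNko TGFB+ (3292 genes) it was also 1 of 10 with a highest other of 0, and for IFNko TGFB1 KO against TGFB KO (684 genes) 1 of 10 with a highest other of 1. For IFNko TGFB+ against wild type, 10 of 10 splits gave as many, namely 0 (limma; 649 genes at an unadjusted p under 0.05). A real count of 0 is reached by any split, so this says nothing on chance. For the difference of effects, 13 of 100 regroupings drawn from 200 gave at least the real 111 genes, with a highest other of 224, a share that by itself does not exclude chance. All 13 are among the 15 drawn that kept the TGFB KO and IFNko TGFB1 KO arrays apart; these hold the real difference between those groups, so the share does not measure chance. Of the regroupings that mixed these arrays 0 reached as many, with a highest of 1. Mixing puts the real difference between those groups into the spread within groups, so these low counts do not measure chance either.

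Genes of a donor strain beside a disrupted gene could appear as calls near it. In the window of 100 tested genes around Ifng, with Ifng itself not counted, 5 had an unadjusted p under 0.05 in IFNko TGFB+ against wild type. All windows of 100 neighbouring genes had a median of 5 and a 95th percentile of 9. In the window around Tgfb1, with Tgfb1 not counted, 16 were called in the same direction in both TGFB comparisons. The median was 15 and the 95th percentile 23 over 10715 windows. Neither count lies above the 95th percentile. A few linked genes could stay under these limits, so the counts do not exclude them.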
